A study of Mus musculus with 42 samples.

How the data were processed

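The samples were mouse embryonic stem cells (ESC) and embryoid bodies, aggregates that form and differentiate once leukaemia inhibitory factor (LIF) is withdrawn. Per the labels, 2 wild-type lines (W1 and W2) and 2 lines without AMPK catalytic activity (K1 and K3, DKO) were collected as ESC (day 0) and as embryoid bodies on days 2, 4, 8 and 12, in medium with 25 mM glucose (HG) or 2.5 mM glucose (LG). The ESC had been kept on irradiated feeder cells and passaged without feeders before collection. Libraries were made from messenger RNA with a TruSeq kit that does not mark strand, so that reads from a gene and an overlapping or antisense partner cannot be told apart. Values of such genes, and of genes with near-identical copies, are uncertain.

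The deposited table held RPKM values (reads scaled to transcript length and to the number of mapped reads) for 24225 genes in 42 libraries, with mm10 coordinates, per the file headers. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.0k, HOMER, edgeR 3.6.8, R 3.1.1 and the builds mm10 and GRCm38, without their roles. Gene filters and the handling of reads with several positions were not given in the sources used here. RPKM values are not counts, and a shift of a few abundant transcripts moves the values of all others. Low values of genes between 200 and 1500 nt long, at up to 5 reads, were whole multiples of 1 read in 100% of cases within 0.1 read. The steps gave depths between 10500000 and 25300000 reads per library, with a median of 15350000, so that 1 RPKM over a transcript of 1 kb stood for 10.5 to 25.3 reads. No count model was run. The RPKM sums lay between 279334 and 340677, and 11463 to 13119 genes reached 1 RPKM in a library.

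Columns were assigned to samples by their headings alone. A total of 6 headings, all of day 4, stood over 2 columns each, and the order of the samples behind such a pair was not given, so the pair was averaged on the log scale as 1 value of its line. No other library was counted more than once, since 0 pairs of libraries were identical and the largest Pearson r between 2 libraries across genes was 0.9901. The headings were then compared with the expression of 8 genes that separate the lines (Ddx3y, Eif2s3y, Kdm5d, Uty and Zfy1 of the Y chromosome, and the imprinted RNAs Meg3, Rian and Mirg) and with Txnip, a transcript induced by glucose, at a threshold of 5 RPKM. No library was moved to another group. All comparisons were made with every library under its heading ("as labelled"), and again with the 24 libraries whose line markers and Txnip both matched the heading ("label-matched"). The second set was chosen after the data were seen, and the marker genes themselves are no independent result in it. In it, WT LG days 8 and 12 rested on W1, DKO HG days 8 and 12 on K3, and no comparison of HG days 0, 2 or 4 between genotypes could be made. At days 8 and 12 the line markers alone left out the same libraries as line markers and Txnip together.

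Tests were made on log2(RPKM + 1), so fold changes of low genes are understated. Genes with at least 1 RPKM in at least 2 values were kept, 14914 as labelled and 14670 in the label-matched set. The limma package (3.58.1, R 4.3.3) fitted means of 18 groups to 36 values, 1 per line and condition, with a mean-variance trend and 18 residual degrees of freedom. The label-matched fit had 23 values and 9 residual degrees of freedom. Both fits treated the values of one line over days and glucose levels as independent, although in the label-matched set they were correlated, as given below. The degrees of freedom thus overstate the independent differences between lines, and p-values of single conditions may be too small. In an arm with 1 line, that line was assumed to vary like the other groups. The mean over embryoid body conditions was tested on 1 value per line, 2 lines against 2. The genotype by day test was an F test over 4 days. All p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. They measure only the spread between these lines and samples. SD values are over the values of lines.

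Before the data were examined, the model, the comparisons, 31 gene lists, the alternatives and the rule for named genes were written down. The rule takes, for the comparisons it lists, the 8 largest rises and the 8 largest falls among genes past the threshold that average at least 1 RPKM, have a proper symbol and separate all lines. It adds up to 4 members with the smallest p in each list and 14 genes reported in every comparison: Prkaa1, Prkaa2, Tfeb, Tfe3, Lamp1, Ctsd, Pou5f1, Nanog, T, Sox17, Afp, Pax6, Axin2 and Txnip. The same rule was applied to comparisons added with the label-matched set. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and members were also counted with p adjusted over the list alone. Gene positions along chromosome 6 were examined after that chromosome stood apart in one line. For these, genes with a mean of at least 3 RPKM were used and each line was set against the mean of the WT lines.

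The fits were tested on simulated data in which 200 genes were changed. In the label-matched design, LG day 2 recovered 71% of genes changed by 1 and 96% of those changed by 2 on the log2 scale, and LG day 12 recovered 51% and 90%. With all libraries as labelled, the shares were 25% and 70% at LG day 2 and 26% and 71% at LG day 12. The simulated changes followed the headings, so the as-labelled shares hold only if every heading gives the right genotype. The line markers went against some headings, so recovery in the as-labelled data was not measured. False calls were between 1% and 7.6% of all calls. The simulated spread was the one the fit had estimated, alike in every group, with no shifted stretches of chromosomes in a line. Recovery and false calls therefore hold only where the real data meet these assumptions.

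The replicate number is the number of the cell line, so it pairs samples of one line across days and glucose levels. In the label-matched set, the correlation of deviations from the group mean was 0.12 to 0.42 for W1 and W2 over 10 pairs of conditions, and 0.17 to 0.64 for K1 and K3 over 6. As labelled, it ran from -0.74 to 0.89 for the WT lines and from -0.23 to 0.74 for the DKO lines. Alternatives were another pseudocount, other filters, median-of-ratios and quantile scaling, each line left out, separate values, a line block, a random line effect, either column of day 4, and subsets by the markers. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots. Some genes that the rule names are not reported here.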

Results

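Messenger RNA was measured by sequencing in 42 libraries from 4 mouse ES cell lines, 22 labelled WT and 20 labelled DKO. The DKO lines lack both catalytic subunits of AMPK, a kinase that senses low cellular energy, encoded by Prkaa1 and Prkaa2. The series title links AMPK to Tfeb, a transcription factor of lysosomal genes, and to lineage specification. The lines were sampled as ESC and on days 2, 4, 8 and 12 of embryoid body culture in 25 mM (HG) or 2.5 mM (LG) glucose, which gave 18 groups and 9 conditions. By heading there were 11 libraries of W1, 11 of W2, 11 of K1 and 9 of K3, at depths of 10500000 to 25300000 reads. Each genotype had 2 lines, and the line was the replicate. The spread in tests of single conditions was pooled over repeated values of these 4 lines.

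Prkaa2 (chromosome 4, 105029650 to 105109898, mm10), which encodes an AMPK catalytic subunit, was measured in every library first. In libraries labelled W1 it was at 2.02 RPKM in ESC, 2.36 at HG day 2, 2.79 and 2.62 at HG day 4, 8.1 at HG day 8, 10.5 at HG day 12, 1.76 at LG day 2, 3.56 and 5.77 at LG day 4, 18.4 at LG day 8 and 22.3 at LG day 12. In libraries labelled W2 it was at 12.6 RPKM in ESC, 0.423 at HG day 2, 2.56 and 0.274 at HG day 4, 7.96 at HG day 8, 12.5 at HG day 12, 1.32 at LG day 2, 2.71 and 2.02 at LG day 4, 0.416 at LG day 8 and 0.04 at LG day 12. In libraries labelled K1 it was at 0.019 RPKM in ESC, 2.38 at HG day 2, 5.01 and 3.39 at HG day 4, 2.38 at HG day 8, 0.555 at HG day 12, 0.041 at LG day 2, 0.057 and 0.055 at LG day 4, 0.121 at LG day 8 and 0.056 at LG day 12. In libraries labelled K3 it was at 18.1 RPKM in ESC, 0.065 at HG day 2, 0.015 at HG day 4, 0.901 at HG day 8, 0.793 at HG day 12, 0.187 at LG day 2, 0.233 at LG day 4, 0.959 at LG day 8 and 0.617 at LG day 12. Thus 4 of 22 libraries labelled WT lay below 1 RPKM, and 15 of 20 labelled DKO did. Prkaa1 (chromosome 15, 5143861 to 5181899) kept 4.01 RPKM or more in every library and reached 14.7 in the library labelled K1, HG day 4. Gene-level values include reads from exons outside a deletion, and the deleted exons were not given in the sources used here.

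The headings and the expression of line markers disagreed in 15 libraries. Y-linked Ddx3y, an RNA helicase gene, lay between 0.895 and 1.6 RPKM in libraries with the K1 pattern, 2.53 and 4.67 with the W1 pattern, 5.44 and 8.72 with the W2 pattern, and 10.8 and 20.2 with the K3 pattern. The imprinted RNA Meg3 was at most 0.308 RPKM with the W2 pattern and at least 18.5 with the other patterns. Txnip, a glucose-induced inhibitor of thioredoxin, was at most 2.18 RPKM in 19 libraries and at least 19.9 in 23, and it went against the heading in 8 libraries, 5 of which were also contradicted by the line markers. The 18 contradicted libraries filled 10 of 11 neighbouring places of the table and 8 of 8 neighbouring places further on, with 0 of 23 elsewhere. In the 24 libraries matched by both, Prkaa2 was 1.32 to 22.3 RPKM in 13 libraries labelled WT and 0.019 to 0.959 in 11 labelled DKO, and Prkaa1 was 6.53 to 11.2 and 4.01 to 6.63 RPKM.

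**Figure D1:**
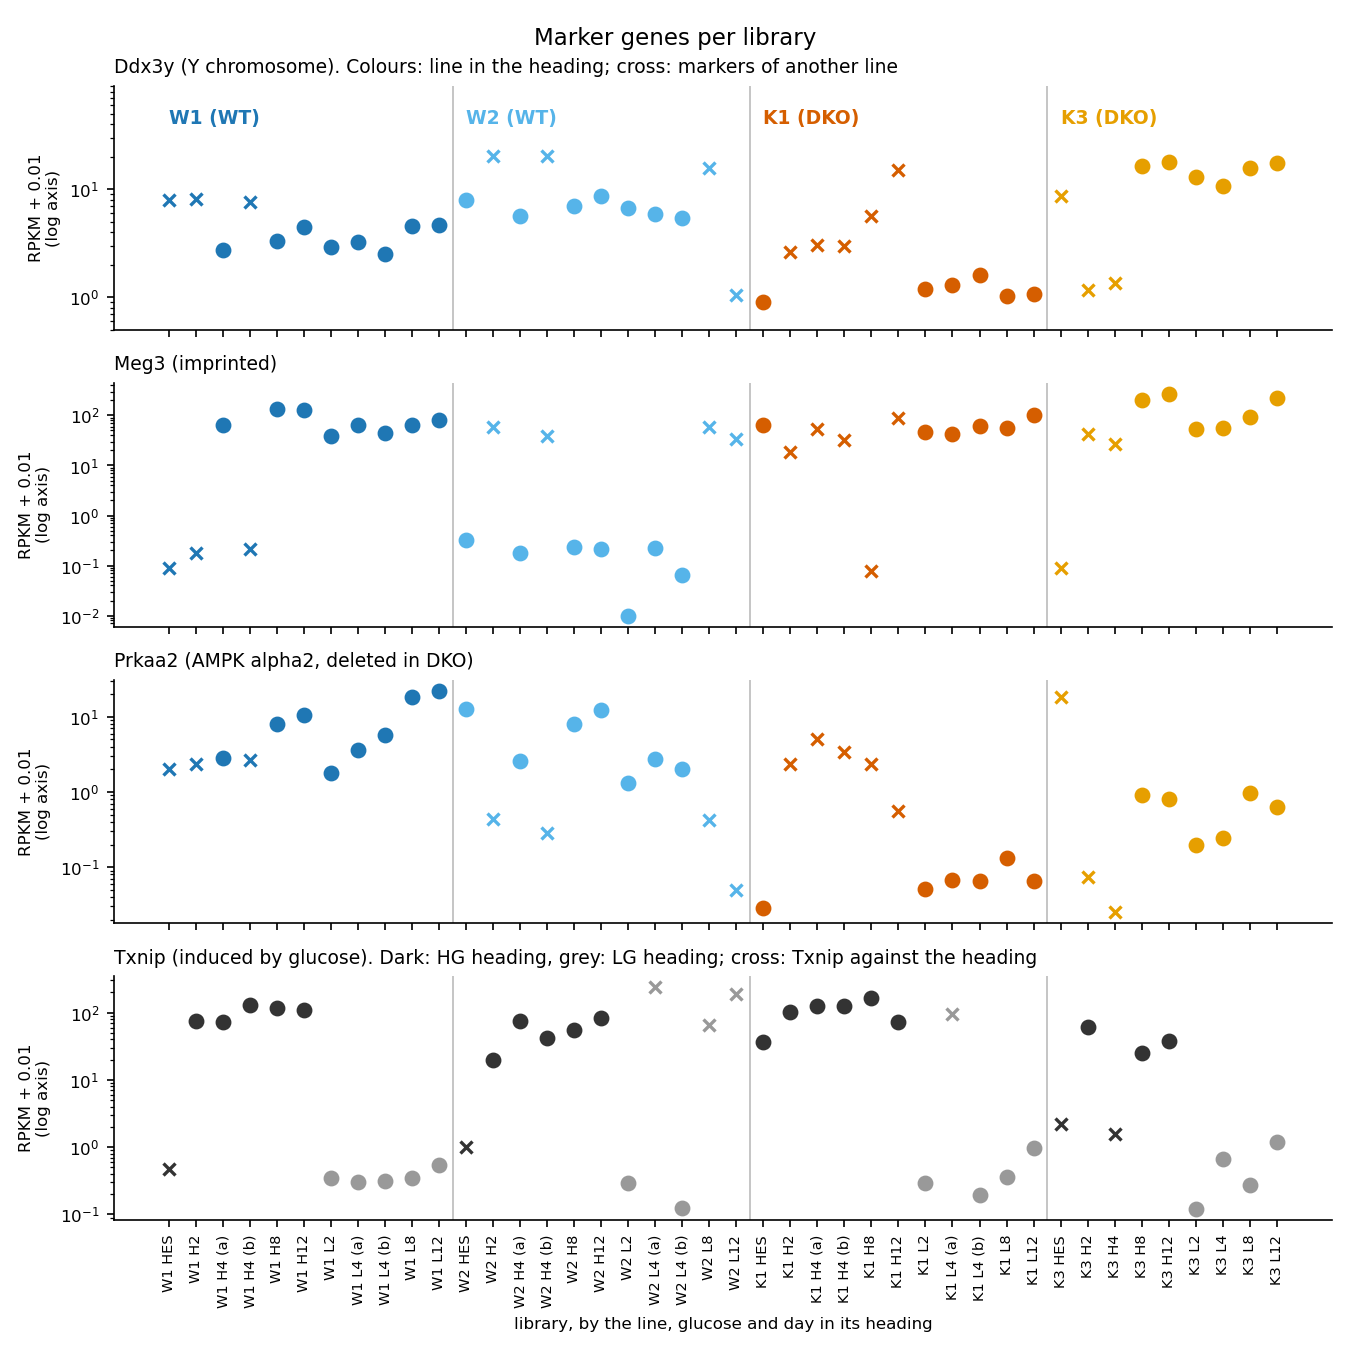
RPKM of Ddx3y, Meg3, Prkaa2 and Txnip in each of the 42 libraries, on log axes, grouped by the heading of the library. Crosses mark the 18 libraries contradicted by line markers or Txnip, such as the library labelled W2, LG day 12, with Prkaa2 at 0.04 RPKM.

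Directions as labelled therefore mix lines in the ESC, at HG days 2 to 12 and at LG days 8 and 12, and glucose levels in the ESC and at days 4 to 12. Some of the contradicted libraries also stood apart from others of their heading's day in genes of differentiation. The library labelled W2, LG day 12, had Pou5f1 at 342 RPKM and Afp at 0, against 16.2 and 1530 in W1, and that labelled W2, LG day 8, had 445 and 0, against 64.1 and 284 in W1. The library labelled K1, HG day 12, had 381 and 0, against 67.2 and 193 in K3. The ESC library labelled W2 had 31.2 and 240, and that labelled K3 had 10.9 and 3043, against 311 and 1.73 in K1. At HG day 4, the later-listed columns labelled W1 and W2 had the mesoderm gene T at 0.237 and 0.146 RPKM. The earlier-listed columns had it at 20.5 and 47.7 RPKM. The day under the heading is therefore also in doubt for these libraries. No test of the day was made in the other contradicted libraries. The ESC library labelled K1 matched its markers and filled the remaining place of the first stretch, so its day is open to the same doubt. Among label-matched comparisons it entered only day 12 against ESC in DKO, given with the alternatives. The label-matched set was chosen after the data were seen.

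At LG day 12, label-matched DKO embryoid bodies (K1 and K3) had higher levels of transcripts of pluripotent cells and lower levels of those of endoderm than W1. Pou5f1 (chromosome 17, 35506032 to 35510777), a core pluripotency factor, was 116 ± 24.7 RPKM (SD, n = 2 lines) against 16.2 in W1, a log2 change of 2.75 ± 0.35 (SE, limma adjusted p = 0.000242). Nanog (chromosome 6, 122707489 to 122714633), a factor of the same network, was 49.8 ± 4.26 against 3.22 RPKM (3.59 ± 0.2, adjusted p = 2.34e-06), and it lies in a stretch of chromosome 6 raised in K1. Afp (chromosome 5, 90490714 to 90508907), the alpha-fetoprotein of visceral endoderm, was 36.4 ± 15.1 against 1530 RPKM (-5.41 ± 1.34, adjusted p = 0.00874). Sox17, an endoderm factor, fell by 2.48 ± 0.83 (adjusted p = 0.0355), while T, the mesoderm factor brachyury, rose by 2.52 ± 0.55 (adjusted p = 0.00455) and the Wnt target Axin2 by 1.4 ± 0.46 (adjusted p = 0.0343). Pax6, a neural factor, was at 1.38 ± 0.57 (adjusted p = 0.0775). As labelled, Pou5f1 was at 0.59 (adjusted p = 0.87), Nanog at 0.91 (adjusted p = 0.8), Afp at -0.13 (adjusted p = 0.994), Sox17 at -0.09 (adjusted p = 0.991) and T at 2.91 (adjusted p = 0.105), so none of these passed.

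Lysosomal genes fell in the same comparison. Of 59 tested, 45 were lower and 0 higher (50 lower, adjusted over the list alone), with a median log2 change of -1.58 (camera adjusted p = 1.75e-20, and adjusted p = 0.354 with an estimated correlation). Lamp1 (chromosome 8, 13159135 to 13175338), a lysosomal membrane protein, was 201 ± 4.07 against 745 RPKM (-1.88 ± 0.3, adjusted p = 0.000841). Ctsd (chromosome 7, 142375916 to 142387870), the protease cathepsin D, was 138 ± 49.1 against 464 RPKM (-1.79 ± 0.39, adjusted p = 0.00468). The glycan-degrading enzymes Hexa and Naglu changed by -2.6 (adjusted p = 0.000308) and -2.41 (adjusted p = 0.000231). Of 17 subunits of the V-ATPase, the proton pump of lysosomes, 14 were lower (14 adjusted over the list alone), among them Atp6ap1 (-1.77, adjusted p = 0.000357), with a camera adjusted p = 4.16e-08 and adjusted p = 0.354 with an estimated correlation. Tfeb (chromosome 17, 47785744 to 47792416) was 3.9 ± 2.54 against 11.6 RPKM (-1.46 ± 0.47, adjusted p = 0.0309), and its relative Tfe3 was at 0.03 ± 0.16 (adjusted p = 0.905). Of the 4 MiT/TFE factors, 2 were lower (2 adjusted over the list alone), Tfeb and Mitf (-1.12, adjusted p = 0.0136), with a camera adjusted p = 0.0961. Mitf lies in a stretch of chromosome 6 lowered in K1. The V-ATPase genes Atp6v1f and Atp6v0e2 lie in one lowered in K3, and were at -1.22 and -1.69 in K3 and -0.1 and -0.22 in K1 over the LG days. Atp6v1e1 lies in a stretch raised in K1, and was at -0.15 in K1 and -0.72 in K3. As labelled, Lamp1 was at -0.52 (adjusted p = 0.766), Ctsd at -0.74 (adjusted p = 0.609) and Tfeb at -0.48 (adjusted p = 0.794), and the lysosomal median was -0.55 with 1 gene lower (camera adjusted p = 1.57e-06, adjusted p = 0.659 with an estimated correlation).

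The gene lists of cell types moved apart at LG day 12. Of 28 genes of visceral and extraembryonic endoderm, 16 were lower and 0 higher (20 lower, adjusted over the list alone), including the plasma protein genes Fgb (-4.54, adjusted p = 0.00022) and Trf (-5.48, adjusted p = 0.000284), with a median of -3.61 (camera adjusted p = 1.06e-10). Of 17 genes of definitive endoderm and gut, 9 were lower (9 adjusted over the list alone, with 1 higher), among them the gut factors Foxa3 (-2.28) and Foxa2 (-2.43) (camera adjusted p = 0.00321). Of 24 genes of naive pluripotency, 16 were higher and 1 lower (16 and 1 adjusted over the list alone), and of 15 of the formative epiblast 10 were higher (15 adjusted over the list alone), with camera adjusted p = 0.00019 and 6.98e-05. Examples are Utf1 (2.48), Lin28b (2) and the DNA methyltransferase gene Dnmt3b (2.36). Of 19 mesoderm genes 13 were higher and 1 lower (15 and 1 adjusted over the list alone), among them Prrx1 (3.03) and Isl1 (2), with a camera adjusted p = 0.000201. Of 23 Wnt targets 14 were higher and 1 lower (16 and 1 adjusted over the list alone), led by the nuclear effectors Tcf7 (1.8) and Lef1 (3.59) (camera adjusted p = 0.00321). Of 24 neural genes 8 were higher (8 adjusted over the list alone), such as Stmn2 (2.15) and Nes (1.52), and of 22 cell cycle genes 12 were higher (15 adjusted over the list alone), such as Mcm6 (0.98), with camera adjusted p = 0.0145 and 0.00019. With an estimated correlation the adjusted p was 0.354 for these lists and 0.574 for the neural genes.

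In all, 5183 genes differed at LG day 12 in the label-matched libraries, 3278 higher and 1905 lower, or 2415 and 2440 under median-of-ratios scaling and 2900 and 2364 under quantile scaling. The median of all genes was 0.16, and 0.05 under median-of-ratios scaling. The largest falls included Gkn2 (-7.39 ± 0.5) and Gkn1 (-5.61), gastrokine genes within the chromosome 6 segment given further on, and the largest rises included Lef1, Nanog, Ifitm1 (3.42), Crabp1 (3.31) and Tdgf1 (3.13). As labelled, 572 genes were called, 500 higher and 72 lower (351 and 113 under median-of-ratios scaling). There, Axin2 rose by 1.84 (adjusted p = 0.0303) and 5 mesoderm genes were higher (9 adjusted over the list alone), among them Prrx1 (3.04) and Twist1 (3.22), while 1 lysosomal gene was lower, Tmem192 (-1). The library labelled W2 at this day was contradicted by line markers and by Txnip. Without W2 the label-matched count was 2413. As labelled it was 1 without W1, 5 without W2, 1036 without K1 and 311 without K3.

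At HG day 12, label-matched K3 differed from W1 and W2 in the same directions for these genes. Pou5f1 was 67.2 RPKM against 9.26 ± 3.55 (SD, n = 2 lines; 2.78 ± 0.35, adjusted p = 0.000391) and Nanog 35.4 against 3.36 ± 0.34 RPKM (3.06 ± 0.2, adjusted p = 6.32e-06). Tfeb was 3.45 against 16 ± 0.0672 RPKM (-1.93 ± 0.47, adjusted p = 0.0101), Lamp1 165 against 373 ± 63.5 (-1.16 ± 0.3, adjusted p = 0.0125) and Ctsd 131 against 297 ± 13.5 (-1.18 ± 0.39, adjusted p = 0.0375). Afp was 193 against 2040 ± 952 RPKM and did not pass (-3.31 ± 1.34, adjusted p = 0.0759). Txnip fell by 1.31 ± 0.34 (adjusted p = 0.0135) and Pax6 rose by 2 ± 0.57 (adjusted p = 0.0203). Of 59 lysosomal genes 34 were lower and 1 higher (41 and 2 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 5.73e-12, adjusted p = 0.486 with an estimated correlation). Of 24 neural genes 16 were higher (17 adjusted over the list alone), such as Stmn2 (3.58) and Fabp7 (2.94), and of 26 cardiac and muscle genes 16 were higher (16 adjusted over the list alone), such as the atrial and contractile genes Myh6 (2.87) and Actc1 (2.98), with camera adjusted p = 1.41e-05 and 0.000234 (adjusted p = 0.486 with an estimated correlation). Of 16 feeder and fibroblast genes 8 were lower and 2 higher (8 and 2 adjusted over the list alone), with the collagen gene Col1a1 at -5.43 (camera adjusted p = 0.000706, adjusted p = 0.486 with an estimated correlation).

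In all, 4730 genes differed at HG day 12 in the label-matched libraries, 2969 higher and 1761 lower, or 2099 and 2319 under median-of-ratios scaling and 2744 and 2169 under quantile scaling. Among the largest falls were the imprinted genes Peg10 (-8.44) and Mest (-6.86), both in a stretch of chromosome 6 lowered in K3, and Trf (-5.64). As labelled 534 genes were called, 217 higher and 317 lower (558 and 575 under quantile scaling). There, 3 of 28 visceral endoderm genes were lower (8 adjusted over the list alone), among them Fgg (-3.32) and Trf (-5.96), and 2 of 59 lysosomal genes were (4 adjusted over the list alone), Galns (-2.65) and Cd68 (-1.41). Pou5f1 was at 4.02 (adjusted p = 0.0823), Nanog at 3.96 (adjusted p = 0.0908), Tfeb at -2.27 (adjusted p = 0.0725), Lamp1 at -1.22 (adjusted p = 0.235) and Ctsd at -1.24 (adjusted p = 0.201) as labelled. The library labelled K1 at this day had the K3 pattern of markers. Without W1 or W2 the label-matched count was 574 or 492. As labelled it was 35 without W1, 6 without W2 and 126 without K3. The calls of LG day 12 and HG day 12, which share no libraries but both rest on lines W1 and K3, had 2119 genes higher in both, where independent lists would share 663, and 1144 lower in both, where 229 would be shared. Fixed differences between these lines, chromosome 6 included, add to this overlap, so the independent lists are no value for an absent genotype effect. Calls in opposite directions numbered 17.

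**Figure D2:**
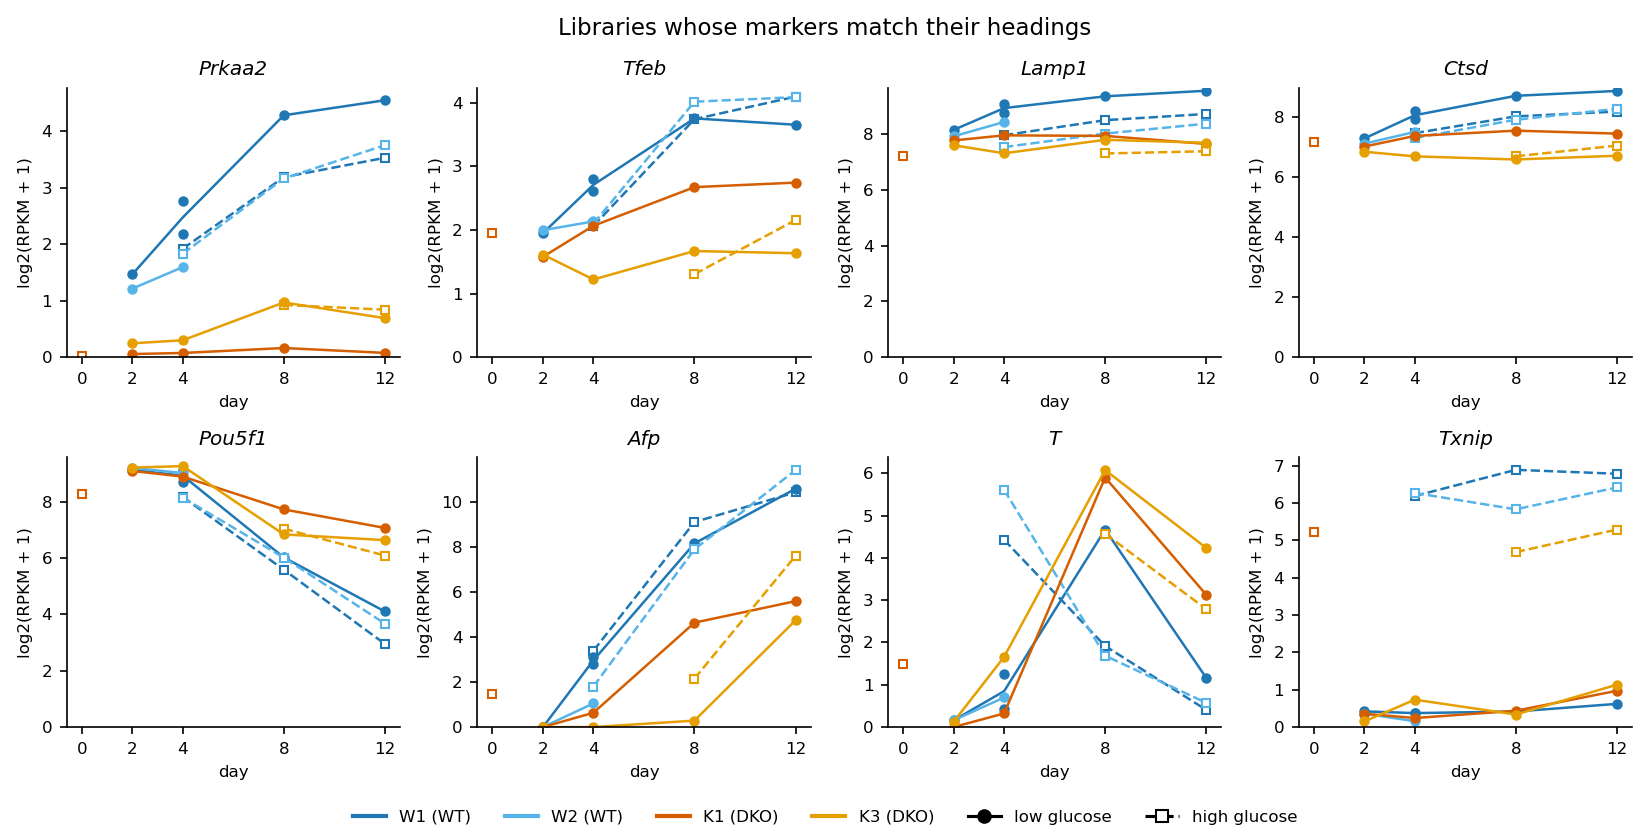
Log2(RPKM + 1) of 8 genes by day of embryoid body culture in the label-matched libraries, 1 line per cell line, solid with filled points for LG and dashed with open points for HG. Afp reached 1530 RPKM in W1 at LG day 12 and stayed at 36.4 RPKM on average in K1 and K3.

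The early LG days had 2 lines in each arm. At LG day 2, Pou5f1 was 574 ± 20.1 RPKM in WT and 570 ± 33.8 in DKO (SD, n = 2 lines each). A total of 22 genes differed, 1 higher and 21 lower. Of 18 targets of p53, 1 rose, Ccng1, a cell cycle regulator (0.91, adjusted p = 0.0348), and 9 were higher adjusted over the list alone, with Cdkn1a, the inhibitor p21, at 1.37 (adjusted p = 0.0601). The list had a median of 0.45 (camera adjusted p = 7.13e-12, adjusted p = 0.538 with an estimated correlation). None of 59 lysosomal genes passed, and 0 did adjusted over the list alone, with a median of -0.29 (camera adjusted p = 1.31e-05, adjusted p = 0.986 with an estimated correlation). Lamp1 was at -0.35 ± 0.24 (adjusted p = 0.935). As labelled, limma called 0 genes, with 163 at an unadjusted p under 0.05, and the p53 list had a camera adjusted p = 2.21e-15 (adjusted p = 0.079 with an estimated correlation). Without K1 the as-labelled count was 4. The label-matched count was 1 without W1, 0 without W2, 415 without K1 and 34 without K3. Of the 22 genes, 15 lie in the chromosome 6 segment.

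At LG day 4, 245 genes differed in the label-matched libraries, 56 higher and 189 lower. Of 59 lysosomal genes 10 were lower (28 lower and 1 higher, adjusted over the list alone), including Hexa (-1.95, adjusted p = 0.00867) and Arsa (-1.39), with a median of -0.65 (camera adjusted p = 2.35e-19, adjusted p = 0.65 with an estimated correlation). Lamp1 was 201 ± 62.6 against 413 ± 99.9 RPKM and did not pass (-1.05 ± 0.24, adjusted p = 0.0549). Rragc, a GTPase that recruits mTORC1 to lysosomes, fell by 1.07 (adjusted p = 0.0022). The p53 targets Cdkn1a (1.2, adjusted p = 0.0384) and Ccng1 (0.69) rose, 2 of 18 (4 adjusted over the list alone). The insulin-like growth factor Igf2 fell by 2.41 ± 0.41 (adjusted p = 0.0198), the phosphatase gene Dusp4 by 2.37 ± 0.25 (adjusted p = 0.00179) and Gstt2 by 2.06 ± 0.2 (adjusted p = 0.00098). The BMP antagonist Grem1 rose by 1.87 ± 0.25 (adjusted p = 0.00569). As labelled limma called 0 genes, with 248 at an unadjusted p under 0.05, and 1 without K1. With libraries selected by line markers alone 28 were called. The label-matched count was 1 without W1, 15 without W2 and 1487 without K1.

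At LG day 8, 43 of 59 lysosomal genes were lower in the label-matched libraries (50 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 2.82e-24, adjusted p = 0.338 with an estimated correlation). Afp changed by -5.69 (adjusted p = 0.0146), Tfeb by -1.58 (adjusted p = 0.0375) and Lamp1 by -1.49 (adjusted p = 0.00752), and Nanog rose by 1.67 (adjusted p = 0.000916). Of 20 hypoxia targets 7 were lower (10 adjusted over the list alone), among them Ndrg1 (-2.38) and P4ha1 (-2.17), with a camera adjusted p = 2.51e-05 (adjusted p = 0.406 with an estimated correlation). In all 2772 genes differed, 1607 higher and 1165 lower (964 and 1526 under median-of-ratios scaling, 1440 and 1357 under quantile scaling). As labelled 52 did, 48 higher and 4 lower, among them the primitive streak genes Nkx1-2 (3.59, adjusted p = 0.0124) and Tbx6 (0.9, adjusted p = 0.0495), while Afp was at -1.62 (adjusted p = 0.899), Tfeb at -0.54 (adjusted p = 0.84), Lamp1 at -0.21 (adjusted p = 0.952) and Nanog at 0.26 (adjusted p = 0.971). Of 19 streak genes 12 were higher adjusted over the list alone (camera adjusted p = 9.38e-10, adjusted p = 0.286 with an estimated correlation). The as-labelled WT arm included the library labelled W2, LG day 8, with K3 markers, Txnip at 65.2 RPKM and Pou5f1 at 445 RPKM. Genotype, glucose level and possibly day are thus mixed in the as-labelled values, and no direction can be drawn from them. Label-matched WT at this day was W1 alone. The label-matched count was 244 without W2 and 4680 without K1. As labelled it was 3 without W1, 2 without W2, 224 without K1 and 14 without K3.

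At HG day 8, Tfeb was 1.47 RPKM in K3 against 13.7 ± 1.98 in the WT lines (n = 2, -2.57, adjusted p = 0.00772), Afp 3.45 against 392 ± 220 (-6.34, adjusted p = 0.0125) and T rose by 2.77 (adjusted p = 0.00968). Of 59 lysosomal genes 27 were lower (43 adjusted over the list alone; camera adjusted p = 6.04e-14, adjusted p = 0.461 with an estimated correlation). In all 2240 label-matched genes differed, 1158 higher and 1082 lower (947 and 1197 under median-of-ratios scaling). As labelled, where the library labelled K1 had the W2 pattern, 2 genes were lower and 0 higher, and Tfeb was at -2.27 (adjusted p = 0.377), Afp at -7.13 (adjusted p = 0.476) and T at 1.43 (adjusted p = 0.532). The lysosomal list had a median of -0.91 there with 0 genes lower (1 adjusted over the list alone; camera adjusted p = 2.8e-08, adjusted p = 0.544 with an estimated correlation). The label-matched count was 116 without W1, 57 without W2 and 4572 without K1. As labelled it was 39 without W1, 0 without W2, 56 without K1 and 6 without K3. K1 had no label-matched library at HG day 8, so leaving K1 out there could act only through the shared spread and the genes kept. In the ESC and at HG days 2 and 4, limma called 0 genes as labelled, with 407, 489 and 122 at an unadjusted p under 0.05, and all 4 libraries of HG day 2 were contradicted by line markers. In the ESC, 10 of 19 streak genes were lower adjusted over the list alone, and T was at -2.86 ± 1 and Axin2 at -1.77 ± 0.46 (adjusted p = 1 each). The libraries labelled W1 and K3 had W2 markers there, and the ESC library labelled K3 held Afp at 3043 RPKM, and that labelled W2 had Pou5f1 at 31.2 RPKM, so no direction was drawn. Without K1 the ESC count was 25, without K3 it was 2 and without W2 1. It was 3 without K3 at HG day 2 and 22 without K1 at HG day 4.

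**Figure D3:**
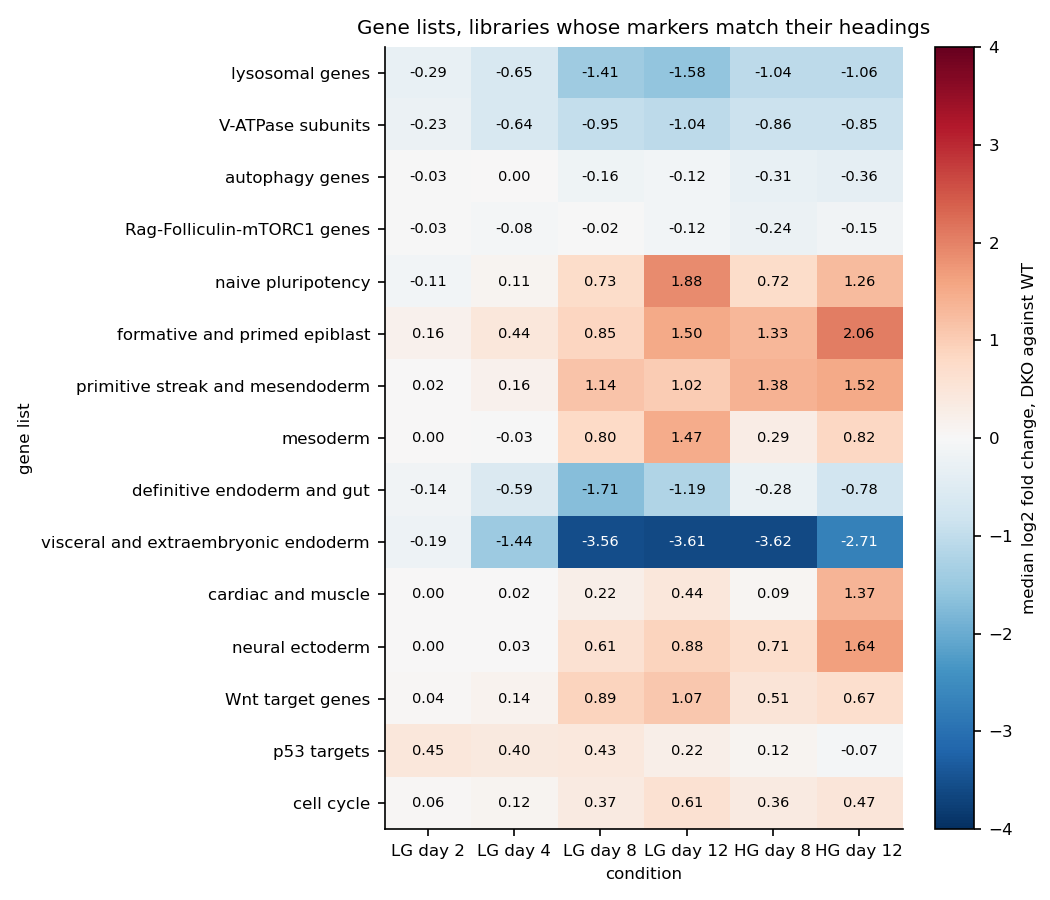
Median log2 fold change, DKO against WT, of 15 gene lists in the label-matched libraries (rows) at LG days 2, 4, 8 and 12 and HG days 8 and 12 (columns), as a colour scale. Lysosomal genes ran from -0.29 at LG day 2 to -1.58 at LG day 12.

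Over all embryoid body conditions, tested on 2 lines against 2, limma called 0 genes as labelled (1223 at an unadjusted p under 0.05, smallest adjusted p = 0.565) and 0 in the label-matched libraries (4471, smallest adjusted p = 0.093). The label-matched value of a line was adjusted for condition but rests on different conditions, since K1 had no HG embryoid bodies, W2 had none at LG days 8 and 12, and HG day 2 had none of any line. Label-matched Prkaa2 was at -2.47, Nanog at 1.44 and Pou5f1 at 1.09 (adjusted p = 0.093 each), Lamp1 at -0.98 (adjusted p = 0.0935), Tfeb at -1.17 (adjusted p = 0.107) and Afp at -2.89 (adjusted p = 0.1). As labelled, Tfeb was at -0.89 ± 0.26 and Prkaa2 at -1.51 ± 0.46 (adjusted p = 0.565 each). The lysosomal list, the question of the series title, had a median of -0.58 as labelled (camera adjusted p = 2.84e-18, adjusted p = 0.573 with an estimated correlation) with 0 of 59 genes lower, 0 adjusted over the list alone, and -0.86 label-matched (camera adjusted p = 4.05e-18, adjusted p = 0.529 with an estimated correlation) with 0 lower, 38 adjusted over the list alone. The as-labelled median was -0.27 without W1 and -0.85 without W2. In the label-matched libraries 4044 genes were called without K1 and 3 without W1.

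In WT embryoid bodies, transcripts of naive pluripotency fell and those of visceral endoderm, fibroblasts and lysosomes rose with time. From HG day 4 to day 12 in label-matched W1 and W2, Pou5f1 fell from 285 ± 3.07 to 9.26 ± 3.55 RPKM (SD, n = 2; -4.85 ± 0.29, adjusted p = 2.53e-07) and Afp rose from 5.98 ± 4.95 to 2040 ± 952 RPKM (8.32 ± 1.09, adjusted p = 6.91e-05). Tfeb rose from 3.23 ± 0.0721 to 16 ± 0.0672 RPKM (2.01 ± 0.39, adjusted p = 0.00108), Lamp1 by 0.8 ± 0.24 (adjusted p = 0.0165) and Ctsd by 0.84 ± 0.32 (adjusted p = 0.0442). Of 59 lysosomal genes 38 rose and 1 fell (41 and 1 adjusted over the list alone; camera adjusted p = 4.8e-08, adjusted p = 0.364 with an estimated correlation), and 14 of 16 fibroblast genes rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.8e-10, adjusted p = 0.22 with an estimated correlation), led by Postn (8.02), Col1a1 (8.02) and Col3a1 (7.81). Of 28 visceral endoderm genes 20 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.51e-07, adjusted p = 0.364 with an estimated correlation). Of 24 naive pluripotency genes 18 fell and 3 rose (19 and 3 adjusted over the list alone; camera adjusted p = 3.42e-06, adjusted p = 0.281 with an estimated correlation). In all 7215 genes changed, 3257 up and 3958 down (3768 and 3294 under median-of-ratios scaling), and the count was 2309 without W1 and 2346 without W2. As labelled, day 12 against ESC gave 407 genes in WT, 284 up and 123 down, such as Col1a1 (6.74 ± 1.8, adjusted p = 0.0483), Trf (4.94) and Eomes, a streak factor (-3.5 ± 0.73, adjusted p = 0.0138). There, 10 of 16 fibroblast genes rose adjusted over the list alone (5 over all genes), 11 of 19 streak genes fell and 1 rose (5 and 1 over all genes). Both ESC libraries labelled WT were contradicted, W1 by its line markers and W2 by Txnip at 0.997 RPKM, and the latter held Pou5f1 at 31.2 and Afp at 240 RPKM. The count was 4 without W1, 5 without W2, 668 without K1 and 622 without K3. In DKO limma called 0 genes as labelled, with 1531 at an unadjusted p under 0.05, and 261 without K1.

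In LG, the rise of lysosomal genes between days 2 and 12 differed between the genotypes in the label-matched libraries. In WT, 45 of 59 rose and 0 fell (46 and 1 adjusted over the list alone; median 1.36, camera adjusted p = 3.27e-07, adjusted p = 0.415 with an estimated correlation). Lamp1 rose by 1.52 ± 0.3 (adjusted p = 0.00102) in WT and was at -0.02 (adjusted p = 0.961) in DKO. Tfeb rose by 1.68 ± 0.47 in WT (adjusted p = 0.00971) and was at 0.59 ± 0.39 in DKO (adjusted p = 0.22). By the test of the difference itself, 22 of 59 lysosomal genes had a lower change in DKO (38 adjusted over the list alone), such as Naglu (-1.96) and Ctsf (-1.63), with a camera adjusted p = 1.56e-16 (adjusted p = 0.393 with an estimated correlation). The difference was -1.53 for Lamp1 (adjusted p = 0.0194), 2.76 for Pou5f1 (adjusted p = 0.00295), 3.2 for Nanog (adjusted p = 8.11e-05) and -5.41 for Afp (adjusted p = 0.0473). For Tfeb it was -1.09 (adjusted p = 0.233).

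Both genotypes changed widely over these days. In WT 7971 genes changed, 4394 up and 3577 down (3675 and 4328 under quantile scaling), and in DKO 7472 did, 4902 up and 2570 down (3865 and 3786 under median-of-ratios scaling, 3398 and 3914 under quantile scaling). The median of all genes was 0.1 in WT, and -0.05 under quantile scaling, and 0.19 in DKO, with 0.02 under median-of-ratios and -0.04 under quantile scaling. Of 19 mesoderm genes 18 rose in DKO (18 adjusted over the list alone; camera adjusted p = 1.26e-08, adjusted p = 0.184 with an estimated correlation). A total of 2700 genes differed between the genotypes in this change, 1807 higher and 893 lower in DKO (1069 and 1296 under median-of-ratios scaling, 1549 and 1345 under quantile scaling), with a median of all genes of 0.17, and 0.04 under median-of-ratios scaling. Day 12 in WT was W1 alone. The WT count was 4770 without W2, and that of the difference 64 without W2 and 4458 without K1. As labelled the difference held 5 genes. The planned test of genotype by day in HG called 9 genes as labelled, 0 up and 9 down at day 12, among them the transporter Slc44a4 (-2.65 ± 0.41, adjusted p = 0.0372), and 200 without K1 and 0 without W2.

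Cardiac and contractile transcripts were lower in low glucose in both genotypes. In label-matched WT libraries of days 8 and 12, 20 of 26 cardiac and muscle genes were lower in LG and 0 higher (23 lower, adjusted over the list alone), with a median of -1.84 (camera adjusted p = 4.46e-14, adjusted p = 0.381 with an estimated correlation). Examples are the atrial light chain gene Myl7 (-4.41 ± 0.35, adjusted p = 4.06e-05), Actc1 (-4.36) and the cardiac factor Nkx2-5 (-1.92). In DKO 18 of 26 were lower (21 adjusted over the list alone), with Myl7 at -5.44 ± 0.35 (adjusted p = 6.61e-06) and a camera adjusted p = 1.1e-24 (adjusted p = 0.122 with an estimated correlation). Txnip, one of the markers of the check, fell by 5.96 ± 0.24 in WT (adjusted p = 1.48e-07) and by 4.27 ± 0.24 in DKO (adjusted p = 4.29e-06), and its relative Arrdc4 by 2.87 in WT (adjusted p = 0.000123). In WT 17 of 59 lysosomal genes were higher and 3 lower in LG (18 and 5 adjusted over the list alone), among them Clcn7 (1.11), Dpp7 (1.55) and Lamp1 (1.05, adjusted p = 0.0069), with a camera adjusted p = 6.57e-06 (adjusted p = 0.675 with an estimated correlation). The same Lamp1 contrast was -0.27 with all libraries as labelled. In DKO 0 of 59 lysosomal genes were higher and 3 lower (0 and 3 adjusted over the list alone; median -0.07, camera adjusted p = 0.759).

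In DKO, sterol synthesis genes and the homeobox gene Hoxb9 were higher in LG. Of 20 sterol genes 7 rose and 0 fell (12 adjusted over the list alone), among them Lss (0.81), with a camera adjusted p = 2.33e-08 (adjusted p = 0.4 with an estimated correlation). As labelled the counts of this list were also 7 and 12. Hoxb9 rose by 2.18 ± 0.17 and Hoxc8 by 1.77 in the label-matched libraries of days 8 and 12. As labelled, over days 2 to 12, Hoxb9 rose by 1.25 ± 0.13 (limma adjusted p = 9.93e-05). Of 17 definitive endoderm and gut genes 5 fell in LG (7 adjusted over the list alone), such as Hhex (-1.6) and Foxa1 (-1.52). In all 2164 genes differed in label-matched WT, 620 higher and 1544 lower in LG (1027 and 1158 under median-of-ratios scaling, 1099 and 1091 under quantile scaling), and 985 in DKO, 266 and 719 (402 and 610, 416 and 626). The count was 160 without W2, 3708 without K1 and 3708 without K3 in WT, and 212 without W1, 207 without W2 and 1489 without K1 in DKO. LG was W1 alone in WT, and HG was K3 alone in DKO, so line and glucose level were partly mixed.

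As labelled, over days 2 to 12, 922 genes differed between glucose levels in WT, 222 higher and 700 lower in LG (361 and 535 under median-of-ratios scaling, 395 and 479 under quantile scaling). Txnip changed by -3.64 ± 0.98 (adjusted p = 0.0333). Tagln, a smooth muscle gene, fell by 2.37 ± 0.43 (adjusted p = 0.00554), and 6 of 26 cardiac and muscle genes were lower (16 adjusted over the list alone; camera adjusted p = 2.03e-07, adjusted p = 0.527 with an estimated correlation). Of 22 genes of the Rag-Folliculin-mTORC1 pathway 2 were higher (4 adjusted over the list alone), Rragb (1.39 ± 0.36, adjusted p = 0.0281) and Lamtor3 (0.42, adjusted p = 0.0119), and the list's camera call was kept with an estimated correlation (adjusted p = 7.9e-06, and adjusted p = 0.0252 with an estimated correlation). This call rests on libraries that include 1 of 2 labelled W2, LG day 4, and those labelled W2, LG days 8 and 12, with Txnip at 237, 65.2 and 190 RPKM, of which the last 2 had K3 and K1 markers. In label-matched WT at days 8 and 12, 6 of the 22 genes were higher and 2 lower (9 and 2 adjusted over the list alone), and the call was lost with an estimated correlation (camera adjusted p = 0.00181, adjusted p = 0.381 with an estimated correlation). The WT count was 116 without W1 and 0 without W2. In DKO 196 genes differed, 105 higher and 91 lower, and 407 with the line as a block. Txnip changed by -4.62 ± 0.98 (adjusted p = 0.0276). The DKO count was 2 without W1, 2 without W2, 81 without K1 and 326 without K3.

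The response to glucose differed between genotypes for 7 genes as labelled, 6 higher and 1 lower in the DKO response, and for 20 with the line as a block. Cdkn1a was among them (1.41, adjusted p = 0.0185), and 6 of 18 p53 targets were higher adjusted over the list alone (camera adjusted p = 0.00614, adjusted p = 0.514 with an estimated correlation). The libraries as labelled include some labelled WT with DKO markers and some labelled DKO with WT markers. In some of both genotypes Txnip went against the heading. Genotype and glucose level are thus mixed in this as-labelled result, and no direction can be drawn from it. At days 8 and 12 in the label-matched libraries 183 genes differed, 98 higher and 85 lower (83 and 100 under median-of-ratios scaling, 87 and 140 under quantile scaling), and 321 with the line as a block. Txnip had a smaller fall in DKO, with a difference of 1.69, against -2.35 for the same contrast as labelled. In this label-matched contrast HG was K3 alone in DKO and LG was W1 alone in WT. A difference between lines and one between genotypes thus cannot be told apart in it. The collagen gene Col1a1 was at 2.59 (adjusted p = 0.00139), Srebf2, a regulator of sterol genes, at 0.84 (adjusted p = 0.0251) and Cdx2, a caudal factor, at 1.78 (adjusted p = 0.00866). Of 59 lysosomal genes 1 was lower, Gusb (-1.13), and adjusted over the list alone 2 were lower and 1 higher (camera adjusted p = 1.43e-07, adjusted p = 0.599 with an estimated correlation). The as-labelled count was 16 without W1, 0 without W2, 0 without K1 and 169 without K3, and the label-matched count was 0 without W2 and 547 without K1.

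Chromosome medians, listed where a line stood apart from the others by over 0.3, were listed as labelled for the Y chromosome alone, with K1 at -1.03 over 5 genes, and in the label-matched libraries for chromosome 6 in K3, at -0.37 over 581 genes. On chromosome 6 of mm10, 68 genes from Gcfc2 to Iqsec1 (81923669 to 90810123) had a median of -0.91 in K1 and -0.88 in K3 against the WT mean, and 63 of them were lower in both lines. Before that segment, 182 genes from 3498393 to 73276907 were at 0.08 in K1 and -0.78 in K3. After it, 26 genes from 91013067 to 100287358 were at -0.79 in K1 and 0.11 in K3, and 109 genes from 106769138 to 125194392 at 0.59 in K1 and 0.08 in K3. Genes named here that lie in these stretches include Gkn1 and Gkn2 in the shared segment and Peg10, Mest, Atp6v1f and Atp6v0e2 in the stretch lowered in K3. Mitf lies in that lowered in K1, and Nanog and Atp6v1e1 in that raised in K1. The shift of a stretch may be part of their change. Over the LG days, Gkn1 and Gkn2 also set the WT lines apart, at 1.5 and 1.69 in W1 and -1.5 and -1.69 in W2. WT at LG day 12 was W1 alone. Nanog was at 1.12 in K1 and 1.16 in K3, where its stretch was not raised. Genes of the shared segment made 33 of the 245 calls of LG day 4, 56 of the 5183 of LG day 12 and 54 of the 4730 of HG day 12.

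**Figure D4:**
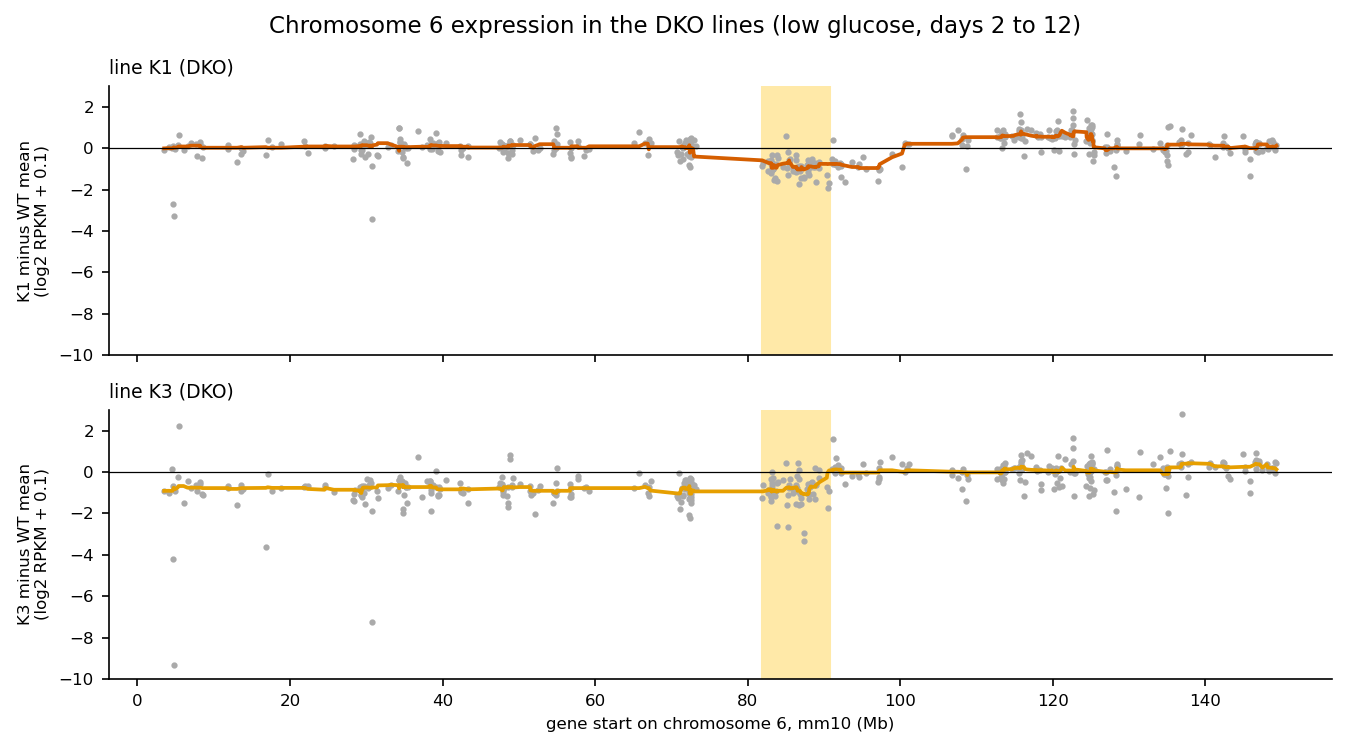
Running median over neighbouring genes of log2 RPKM, K1 and K3 minus the WT mean, along chromosome 6 (Mb, mm10), with the shared segment shaded from 81.9 to 90.8 Mb. Their medians in the segment were -0.91 and -0.88, and they part on either side of it.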

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

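The tests of culture-dependent markers and of the order of the headings, the label-matched comparisons and the counts over splits of the 4 lines were chosen only after the result was seen.

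At day 4, 3 values stood far from the other libraries of their group in 28 checks of a gene in a group, where chance marks about 1 in 20 groups. Prkaa2 was at 0.274 RPKM in a library labelled W2, HG day 4, against 2.56, 2.62 and 2.78 in the others labelled WT. In a library labelled W2, LG day 4, Txnip was at 237 RPKM against 0.114, 0.294 and 0.299, and Nanog at 137 RPKM against 51.5, 55.2 and 60.8.

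The Prkaa2 value lies in a library whose line markers go against the heading, and the other 2 in one of matching line markers, set against its heading by Txnip alone and outside the marker tests given next. Culture-dependent expression of the marker genes is argued against in 9 libraries with markers of the other genotype, where Prkaa2, not among the 8 markers, followed the markers in 9, and in 3 with markers of the other DKO line, where the chromosome 6 flanks followed them in 3. In 3 libraries labelled W1 with W2 markers it stays open, since Prkaa2 set 0 of them apart. Headings put in another order with none added or lost are argued against in the first stretch, where the number of libraries differed between markers and headings in 3 lines, but stay open in the second, where it differed in 0 and the markers of all 8 libraries were 1 line on from the heading in a fixed cycle, with HG in 8 by heading and 7 by Txnip. For the 9 libraries a mislabelled sample is a candidate explanation, since the chromosome 6 segment lay on the side of the marker genotype in 9 of the 9, and whether tubes, libraries or headings were affected stays open.

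Effects differed between groups by a test of the difference in 4 comparisons. Prkaa2, listed below, encodes a subunit that the DKO lines lack, so its difference between genotypes follows from the design. The genotype by glucose test over days 2 to 12 called 7 genes as labelled, and the genotype by day test in HG called 9. Both used libraries whose markers go against their headings. In the label-matched set, WT at LG days 8 and 12 was W1 alone and DKO at HG days 8 and 12 was K3 alone. Line and genotype are therefore partly mixed in the label-matched differences given next. In the label-matched libraries, the change from LG day 2 to day 12 differed between genotypes for 2700 genes, and the response to glucose at days 8 and 12 for 183. Among genes fixed beforehand, the time course in LG differed by 2.76 for Pou5f1 (adjusted p = 0.00295), 3.2 for Nanog (adjusted p = 8.11e-05), 2.61 for T (adjusted p = 0.0257), -5.41 for Afp (adjusted p = 0.0473), -1.53 for Lamp1 (adjusted p = 0.0194) and -2.97 for Prkaa2 (adjusted p = 0.00299), and the response of Txnip to glucose by 1.69 (adjusted p = 0.0371). Leaving out W2 took the first of these label-matched counts to 64 and the other to 0, and leaving out K1 took them to 4458 and 547. As labelled, genotype by glucose gave 16 genes without W1, 0 without W2, 0 without K1 and 169 without K3, and genotype by day gave 0 without W2 and 200 without K1.

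For the glucose comparisons as labelled, HG and LG were exchanged within lines and days. In WT the real split called 922 genes and the highest of the others 281. In DKO it called 196 and the highest other 116, and for genotype by glucose 7 and 4. In each case 1 of 100 splits, the real one, gave as many. This speaks only against HG and LG headings placed at random within a line and day. Columns were not reordered over lines or days, so other orders were not tested. Contradicted libraries stand under both HG and LG headings here. The splits therefore cannot show that glucose, rather than line or day, sets the columns apart. For the mean over embryoid body conditions, the 4 lines allow 3 splits, too few for a share under 0.05. The real split had 1223 genes at an unadjusted p under 0.05 as labelled, with 895 in the highest other, and 4471 label-matched, with 74, so that 1 of 3 splits reached the real value in each set.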

How the results depend on the processing

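Of the alternatives described here, those by day 4 column, by marker match and with all libraries as labelled for the added comparisons were chosen after the data were seen. Of 401 alternatives for 32 counts and list medians, 255 stayed within 1.5 times the main value or kept the call. Of 6991 for 571 single-gene results, 6086 kept direction and side of the threshold, 473 fell short of it, 147 passed it, 270 moved and 15 turned the direction, none of the 15 among the 2981 planned ones for the libraries as labelled. No alternative varied depth, so what it limits was not tested. The cause of the shifts given here was not tested, except that leaving out lines or libraries leaves fewer values. Leaving out a line with no library in a comparison can move its count only through the shared spread and the genes kept.

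With a pseudocount of 0.1, DKO against WT gave 0 genes at HG day 8 (2 in the main result as labelled), 251 at HG day 12 (534), 0 at LG day 8 (52) and 291 at LG day 12 (572). Day 12 against ESC in WT gave 206 (407), LG against HG in DKO 120 (196), genotype by glucose 2 (7), genotype by day in HG 0 (9), and label-matched genotype by glucose 40 (183). With no filter on low values HG day 8 gave 40, LG day 8 gave 111, LG day 12 gave 888, day 12 against ESC in WT 697, LG against HG in DKO 331, genotype by glucose 23, genotype by day 78 and label-matched genotype by glucose 457, and the ESC gave 5 genes, HG day 2 gave 6, HG day 4 gave 3 and day 12 against ESC in DKO 4, each against 0. With a mean of at least 1 RPKM the 9 counts, in the order of the first alternative, were 0, 253, 1, 275, 176, 106, 4, 0 and 105. Median-of-ratios scaling gave 1 gene at HG day 8. Quantile scaling gave 1 at HG day 8, 1133 at HG day 12, and 13 at LG day 2 (22) and 156 at LG day 4 (245) in the label-matched libraries. With day 4 columns as separate values, HG day 8 gave 12, HG day 12 gave 942, genotype by glucose 61, genotype by day in HG 86, and label-matched LG day 4 gave 600.

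With the line as a replicate block, LG against HG in DKO gave 407 genes, genotype by glucose 20, and label-matched genotype by glucose 321. The block moved no other count of calls by over 1.5 times. For the mean over embryoid body conditions (0 as labelled), group means with no line term gave 1289 genes and a random line effect 4. The lysosomal list kept its median of -0.58 with an estimated correlation and lost its call (p = 0.215, and 0.208 by fry, which tests for a common direction). The alternative without the second samples of day 4 was not run, because the headings do not show which column is the second. With only the earlier-listed column, HG day 8 gave 1, HG day 12 gave 279, LG day 8 gave 32, LG day 12 gave 353, day 12 against ESC in WT 195 and LG against HG in DKO 36. With only the later-listed column, the last of these gave 575.

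With only libraries whose line markers match, the ESC gave 3707 genes, HG day 8 gave 1725, HG day 12 gave 4244, LG day 2 gave 18, LG day 4 gave 28, LG day 8 gave 2276, LG day 12 gave 4773, and day 12 against ESC 807 in WT and 3167 in DKO. In the ESC, now K1 against W2, Pou5f1 turned from -1.2 to 3.27, Nanog from -0.73 to 3.57 and Afp from 1.68 to -6.47. The W2 library in that comparison is contradicted by Txnip and held Pou5f1 at 31.2, Nanog at 7.33, Afp at 240 and Ttr at 332 RPKM, against Pou5f1 at 311 and Afp at 1.73 in K1, so these values are no comparison of genotypes in ESC. With line markers and Txnip matching, the counts were 2240, 4730, 22, 245, 2772 and 5183 for HG days 8 and 12 and LG days 2, 4, 8 and 12, and 3595 for day 12 against ESC in DKO. Under both selections Pou5f1 at LG day 8 turned from -0.13 to 1.26. In day 12 against ESC of DKO, which then sets K3 against the ESC library labelled K1 from the first contradicted stretch, it turned from 1.41 to -2.19, Nanog from 1.97 to -1.44 and Afp from -2.71 to 6.15.

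With all libraries as labelled, the added comparisons gave 2279 genes for day 12 against day 4 in WT HG (7215 label-matched), 116 for day 12 against day 2 in WT LG (7971), 2773 in DKO LG (7472), 5 for the difference between genotypes in it (2700), and 1025 and 237 for LG against HG at days 8 and 12 in WT (2164) and DKO (985). In the WT glucose comparison Gkn2 turned from 2.58 to -0.61, Prkaa2 from 1.01 to -1.06 and Lamp1 from 1.05 to -0.27. Txnip turned from 1.69 to -2.35 in genotype by glucose.

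Leaving out 1 line at a time, where a lone line was assumed to vary like the other groups, gave as labelled 0 to 25 genes in the ESC, 0 to 3 at HG day 2, 0 to 22 at HG day 4, 0 to 56 at HG day 8 and 6 to 684 at HG day 12. It gave 0 to 4 at LG day 2, 0 to 1 at LG day 4, 2 to 224 at LG day 8 and 1 to 1036 at LG day 12. Day 12 against ESC gave 4 to 668 in WT and 0 to 261 in DKO, and LG against HG 0 to 1164 in WT and 2 to 326 in DKO. Genotype by glucose gave 0 to 169, genotype by day in HG 0 to 200, and the mean over embryoid body conditions 0 to 0. The lysosomal median ran from -0.85 to -0.27. In the label-matched libraries the ranges were 57 to 4572 at HG day 8, 492 to 6545 at HG day 12, 0 to 415 at LG day 2, 1 to 1487 at LG day 4, 244 to 4680 at LG day 8 and 2413 to 6714 at LG day 12. They were 0 to 4044 for the mean over conditions and 0 to 3 for the mean over LG days. For the time courses they were 2309 to 8708 in WT HG, 4770 to 9344 in WT LG and 5418 to 7070 in DKO LG, and 64 to 4458 for the difference between genotypes. LG against HG gave 160 to 3708 in WT and 207 to 1489 in DKO, and genotype by glucose 0 to 547.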

Other observations

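The tests of chromosome 6, of imprinted genes and of the lysosomal list described here were chosen only after the result was seen. Other gene lists moved at LG day 12 in label-matched K1 and K3 against W1. Of 24 targets of ATF4, the factor of the amino acid response, 6 were lower and 1 higher (5 lower, adjusted over the list alone), with Ddit3 at -1.61 (adjusted p = 0.0016) and a camera adjusted p = 0.0068 (adjusted p = 0.574 with an estimated correlation). Of 32 autophagy genes 9 were lower and 1 higher (9 and 1 adjusted over the list alone), among them Uvrag (-1.11) and Gabarap (-1.21), with a camera adjusted p = 0.0348 (adjusted p = 0.574 with an estimated correlation). Of 22 Rag-Folliculin-mTORC1 genes 5 were higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.197), with Rragb at 1.3 and Rragc and Flcn, the gene of folliculin, at -0.87 and -1.85. Of 20 sterol genes 8 were higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0447), with Hmgcs1 at 1.34 and Insig1, which restrains sterol synthesis, at -2.01. Of 6 AMPK subunits, Prkaa2 and Prkab1 (-1.11) were lower and Prkag2 (1.04) higher (2 and 1 adjusted over the list alone; camera adjusted p = 0.0961). Of 20 endothelial and blood genes 5 were higher and 8 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.0255).

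Of 19 primitive streak genes 5 were higher (5 adjusted over the list alone; camera adjusted p = 0.0447), of 20 hypoxia targets 2 were higher and 4 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.0961), of 5 germ cell genes 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.124), and of 10 immediate early genes 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.172). Of 16 feeder and fibroblast genes 3 were higher and 4 lower, with Col1a1 at -3.18 (3 and 5 adjusted over the list alone; camera adjusted p = 0.174). Of 22 glycolysis genes 4 were higher and 1 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.265), of 10 trophoblast genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.265), of 7 MondoA-ChREBP targets 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.553), and of 18 p53 targets 3 were higher (3 adjusted over the list alone; camera adjusted p = 0.628). Of 29 oxidative phosphorylation genes 2 were higher (0 adjusted over the list alone), of 26 cardiac genes 5 were higher and 3 lower (4 and 3), of 23 imprinted genes 4 were higher and 2 lower (4 and 2), and of 6 sex-linked genes 0 passed by limma (camera adjusted p = 0.867 each). Of 14 surface ectoderm genes 4 were higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.907). With an estimated correlation none of the 31 lists kept a camera call at LG day 12, where the smallest adjusted p was 0.354.

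Of 59 lysosomal genes 10, 43 and 45 were lower in DKO at LG days 4, 8 and 12, with adjusted p = 0.65, 0.338 and 0.354 for the list with an estimated correlation. Since 0 of 59 members lie on chromosome 6, leaving that chromosome out could not move the median over embryoid body conditions, -0.86, and decides nothing about genes of the segment that act on the list. An example, picked after its value was seen, is Rab7, a GTPase of late endosomes and lysosomes, which lies in the segment and changed by -1.37 at LG day 12 (adjusted p = 0.000173). A different cell make-up is another candidate explanation, since visceral endoderm is rich in lysosomes and Afp was low in DKO, but at LG day 2, with Afp at 0 RPKM in WT, the list's median was -0.29 and its call was lost with an estimated correlation (p = 0.227). Loss of AMPK activity, cell make-up, which was not measured, and the segment cannot be told apart for these genes, because both DKO lines carry the segment and Afp differs with the genotype at the later days.

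On chromosome 6, the segment from 81.9 to 90.8 Mb was lower in both DKO lines. An effect of AMPK loss on the genes next to the segment is argued against, since the lines differed there by up to 0.9. The segment is the overlap of longer lowered runs with different ends, from 82 to 100.7 Mb in K1 and from 3.5 to 89.4 Mb in K3. Its shift was near that of the line's own lowered flank, -0.91 and -0.79 in K1 and -0.88 and -0.78 in K3. A separate line variant, such as a lost copy, in each line would give this overlap without an effect of AMPK loss. An added effect of AMPK loss on the segment's genes cannot be told apart from it. All label-matched DKO libraries carry the segment, and its genes were picked for being lower in both lines. The smaller shift of the lines was -0.88, and the smallest over label-matched conditions was -0.8, values that either would give. 

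Before the segment, from 3.5 to 73.3 Mb, K3 alone was lower, and imprinted genes there moved apart. Peg10, Sgce and Mest, expressed from the paternal copy, were at most 8.09% of the lowest WT value in K3, with Peg10 at 0.129 RPKM against 230 in W1 at LG day 12 and Mest at 0.522 against 131. Asb4, expressed from the maternal copy, lay in K3 between 325% (HG day 8, 33.4 RPKM against up to 23.4 in WT) and 1240% (LG day 12) of the lowest WT value, and K1 also held 25.2 RPKM against 4.83 in W1 at LG day 12. Loss of the paternal copy in K3 is a candidate explanation. A change of imprinting without a loss stays open, since K1, with Peg10 at 44 and Mest at 16.1 RPKM at that day, moved the same way in these genes without a shift of that stretch.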
